A study of Mus musculus with 4 samples.

How the data were processed

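Total RNA from freshly dissected mouse dorsal root ganglia was hybridised to Affymetrix mouse arrays, 4 in all, per the labels. The labels put 2 arrays at one level of ganglia, called the sample-1 level here, and 2 at the other level, the sample-2 level, and number the arrays of each level 1 and 2. They do not name the levels, and what the letters before the array number mean is not stated. The values are the intensity per probe set that the authors deposited, on a linear scale. Every array had a mean of 150.0 after its highest and lowest 2% of values were trimmed, so the deposited intensity values had been scaled to a common target. The software and the steps behind them are not given in the sources used here. No detection calls were used, so a low intensity has no call against background. No values were identical between arrays. The ratios of 3' to 5' control probe sets were 1.50 to 1.55 for actin and 0.776 to 0.808 for Gapdh.

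Intensities were taken as log2(intensity + 16). The pseudocount makes fitted differences smaller than the true ratio for dim probe sets. The medians of the arrays on this scale lay within 0.05 of each other, under the limit of 0.15 set in advance, so the deposited scaling was kept. The 64 control probe sets were left out, as were probe sets whose mean lay under the 40th percentile, which corresponds to an intensity of 14.3, leaving 27022 of 45101. Each was fitted with limma 3.58.1 (R 4.3.3; lmFit, then eBayes with an intensity trend), with no covariate, as sample-2 level minus sample-1 level. The fit had 2 residual degrees of freedom, to which the moderated variance added 9.71. Benjamini-Hochberg adjusted p under 0.05 counted as past the threshold.

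Gene names came from the platform annotation. Of the probe sets other than controls, 34945 had 1 symbol, 932 several and 9160 none in that table, and of the 168 past the threshold 152 had 1, 7 several and 9 none. A probe set with none is unnamed here, and no gene was named from a probe set with several. Gene IDs were looked up in a RefSeq gene table of assembly GRCm38.p6, where 34741 matched and 0 symbols needed updating. No coordinates are printed because the files name no build. Each gene was represented by its tested probe set with the highest mean, and 20 further genes had another probe set past the threshold. Probe sets ending in _x_at or _s_at, such as those of H2-T18, Slc4a1, Pcdh8 and S100a8, can match more than 1 transcript.

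Before the data were examined, 32 gene lists with 561 genes in all, the tests, the alternatives and the rule for named genes were fixed. The lists covered HOX genes and other transcription factors, classes of sensory neurons, ion channels, neuropeptides, glia, housekeeping pathways, stress and injury genes, and tissues that a dissection can carry. Each was tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, with an estimated correlation and fry as alternatives. With an estimated correlation, camera is limited to the 2 residual degrees of freedom of the fit. Its smallest unadjusted p was 0.0163 (camera, fibroblast list), so that alternative had little power to call a list. Members past adjusted p 0.05 were counted by each gene's brightest probe set, adjusted over all probe sets and adjusted over the list alone. A member that did not pass can thus have another probe set that did. The rule named the 12 genes with the largest positive and the 12 with the largest negative difference among those past the threshold whose arrays did not overlap between levels and whose higher level lay at or above the median of all probe sets. It also named up to 4 members of each list past the threshold, or the 2 with the largest difference where none passed, and any tested HOX gene. Members of lists that did not pass are named only in part. Alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, centring on array medians, the array number as a block, eBayes without the trend, a minimum of 1.5-fold, probe sets without the suffixes _x_at and _s_at, the mean of all probe sets of a gene for the lists, and leaving out each array in turn. A list without Pvalb was added after the data were seen.

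The probe set fit was tested on simulated data of 4 arrays with 27022 probe sets, of which 200 per round were changed, over 10 rounds. With each probe set's variance drawn from the prior that limma fitted, it recovered 28.1% of 1.5-fold, 65.6% of 2-fold and 99.5% of 4-fold changes, and 5.46% of calls were false. With the variance set to the moderated variance of the real probe set, it recovered 49.8%, 83.8% and 99.8%, and 12.1% of calls were false. The second noise model was the one tried first. The first was added after its share of false calls had been seen, and both are given because the true noise is not known. In a simulation of 32 lists of 20 genes, camera called the 4 shifted by 0.3 and 0 others. Its genes were drawn independently, so it does not test lists whose genes vary together. The estimated correlation in the real data reached 0.757, for the skeletal muscle list. Intervals of medians in the closing section are 95% bootstrap intervals over genes, from 10000 draws. Figures were drawn with matplotlib 3.10.9.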

Results

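Total RNA from freshly dissected mouse dorsal root ganglia, the clusters of sensory neuron cell bodies along the spinal nerves, was measured on 4 Affymetrix mouse arrays. 2 arrays held RNA from ganglia of one level, called the sample-1 level here, and 2 held RNA from ganglia of the other level, the sample-2 level. The labels neither name the levels nor say that the arrays of a level came from separate animals, so p-values measure only the spread between these arrays, which may be technical. The median intensity of the 45101 probe sets lay between 25.9 and 27.3 on the 4 arrays, and the number of arrays limits the precision. The arrays of a level correlated at r = 0.987 at both levels, across the tested probe sets, and arrays of different levels at 0.982 to 0.986. The comparison asked which transcripts differed between ganglia of the 2 levels.

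Hoxd10, a homeobox gene that helps to set positional identity along the body axis, rose from an intensity of 3.48 ± 3.86 (SD, n = 2) at the sample-1 level to 412 ± 2.30 (SD, n = 2) at the sample-2 level. Penk and Cartpt, which encode the precursors of the enkephalin and CART neuropeptides, rose from 99.0 ± 17.7 to 384 ± 59.7 and from 165 ± 7.50 to 586 ± 64.4. S100a9, an abundant calcium-binding protein of neutrophils, rose from 1077 ± 178 to 2291 ± 337. Pmp2, a lipid-binding protein of peripheral myelin, fell from 869 ± 126 to 172 ± 72.1. Pvalb, the calcium-binding protein of proprioceptive neurons and fast muscle fibres, fell from 1484 ± 377 to 461 ± 65.3.

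**Figure D1:**
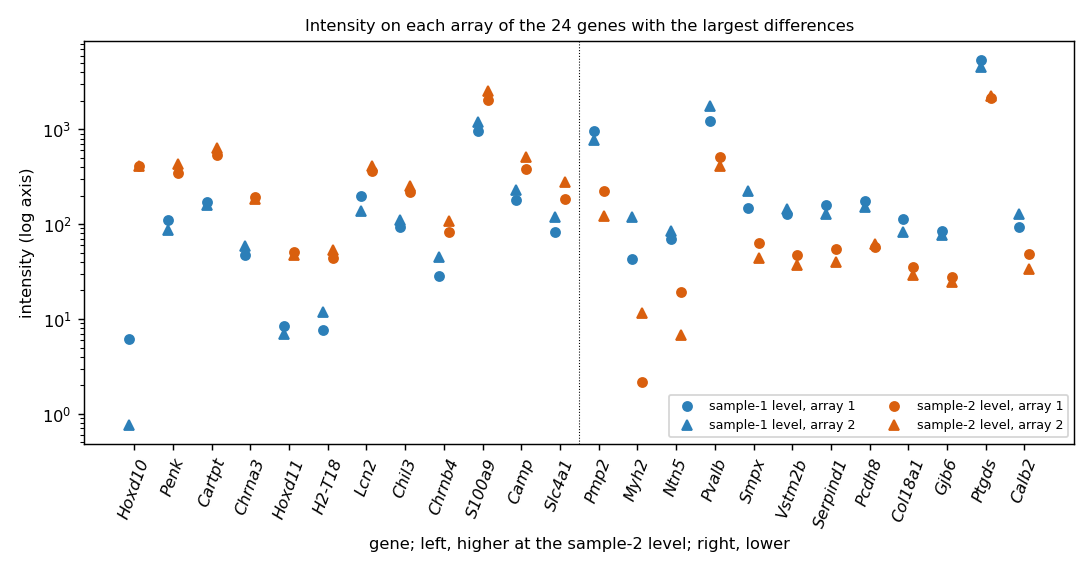
Intensity (log axis) on each of the 4 arrays for 12 genes that rose and 12 that fell at the sample-2 level. Circles mark array 1 and triangles array 2 of a level. These genes had the largest differences among those past the threshold whose arrays did not overlap between levels. Their higher level also lay at or above the median of all probe sets. For each gene both arrays of one level lay above both arrays of the other.

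Of 27022 probe sets tested with limma, 168 passed an adjusted p of 0.05, 60 of them higher and 108 lower at the sample-2 level, and 44 of the 168 differed at least 2-fold on the log2(intensity + 16) scale. An unadjusted p under 0.05 was found for 2933 probe sets, against 1351 from chance. Taken by each gene's brightest probe set, 114 of 13543 genes passed, 40 higher and 74 lower. The number depended strongly on the settings. Without the filter on low signal 4 probe sets passed, those of Hoxd10, Cartpt and Clec2l and an unnamed one (Clec2l lies outside the rule for named genes and is given because of this count). Without the intensity trend in the spread, Hoxd10 alone passed. With a minimum of 1.5-fold 10 passed, 6 higher and 4 lower, and with each array centred on its median 104 passed. With the array number as a block 793 passed, 331 higher and 462 lower. Leaving out array 1 or 2 of the sample-1 level gave 135 and 115 probe sets, and leaving out array 1 or 2 of the sample-2 level gave 241 and 102. Among probe sets with no symbol in the annotation, 1 rose from 4.56 ± 1.23 to 109.8 ± 11.4 and 1 fell from 2055 ± 48.4 to 942 ± 84.9.

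Among 24 tested HOX genes 3 rose and 1 fell. Hoxd10 rose by 4.47 ± 0.18 (log2 difference ± SE, adjusted p = 3.90e-07), Hoxd11 by 1.46 ± 0.24 (adjusted p = 0.0212) and Hoxd9 by 0.87 ± 0.13 (adjusted p = 0.0109). These 3 genes are direct neighbours in the reference annotation (GRCm38.p6). Hoxd8, next to Hoxd9, measured 245 ± 14.4 and 264 ± 6.25, a difference of 0.10 ± 0.11 (adjusted p = 0.81), while its other tested probe set differed by 0.45 and did not pass either. Hoxc8 fell from 113 ± 5.92 to 48.6 ± 4.80 (adjusted p = 0.0205). Hoxa9 at 1279.7 and 1218 and Hoxa10 at 279 and 278 did not pass. Because Hoxd10 and Hoxd11 lay below the filter level of 14.3 at the sample-1 level, their fitted differences depend on the pseudocount, and that of Hoxd10 was 6.86 with a pseudocount of 1. The adjusted p of Hoxd11 with each array left out in turn ranged from 0.0308 to 0.0898, above 0.05 without either sample-2 array, and that of Hoxc8 from 0.0329 to 0.0916, above 0.05 without either sample-1 array.

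As lists, 2 of the 5 tested genes of HOX paralog groups 10 to 13 passed over all probe sets, both higher, and 2 when adjusted over the list alone. The list was shifted up (camera, adjusted p = 3.08e-06), with adjusted p = 0.199 with an estimated correlation. Of the 9 tested genes of groups 6 to 9, Hoxd9 rose and Hoxc8 fell, and adjusted over the list alone 1 was higher and 5 were lower. That list was shifted down (adjusted p = 0.0208), with adjusted p = 0.337 with an estimated correlation, 0.211 without sample-1 array 1 and 0.0979 with the array number as a block. None of the 10 tested genes of groups 1 to 5 passed over all probe sets and 1 was lower adjusted over the list alone. Their list did not pass (adjusted p = 0.229), although it did without the filter on low signal (adjusted p = 0.0228). Hoxb5, with the largest difference in it, measured 231 ± 12.5 and 152 ± 0.984 (adjusted p = 0.0736).

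**Figure D2:**
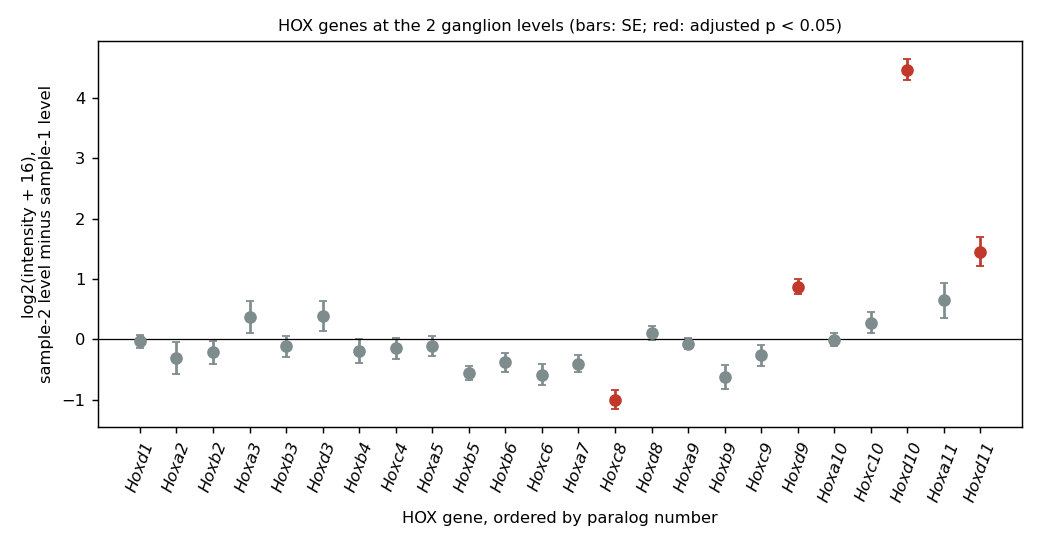
Log2(intensity + 16) at the sample-2 level minus the sample-1 level for 24 tested HOX genes, ordered by paralog number, with bars of 1 SE and genes past adjusted p 0.05 in red. Hoxd9, Hoxd10 and Hoxd11 lie above 0 and Hoxc8 below.

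Several neuropeptide, receptor and channel genes rose. Penk rose by 1.80 ± 0.15 (adjusted p = 0.000187) and Cartpt by 1.73 ± 0.12 (adjusted p = 6.93e-05). Tac1, the substance P precursor, rose from 3487 ± 87.0 to 4376 ± 120.1, a difference of 0.33 ± 0.06 (adjusted p = 0.0463). Trpv1, the heat- and capsaicin-gated channel, rose from 518 ± 15.2 to 875 ± 41.4 (0.74 ± 0.09, adjusted p = 0.00432). Mrgpra3, an itch receptor, rose from 261 ± 0.291 to 390.2 ± 1.87 (adjusted p = 0.0397), Ret, a receptor for GDNF-family ligands, from 2526 ± 71.4 to 3192 ± 42.1 (adjusted p = 0.0498), and Th, tyrosine hydroxylase, from 702 ± 65.6 to 987 ± 47.3 (adjusted p = 0.0461). Chrna3 and Chrnb4, nicotinic acetylcholine receptor subunits, rose from 52.9 ± 8.54 to 189 ± 7.21 (1.57 ± 0.15, adjusted p = 0.000668) and from 36.8 ± 12.4 to 95.2 ± 18.6 (1.08 ± 0.21, adjusted p = 0.0448).

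Of the 18 tested nonpeptidergic nociceptor and pruriceptor markers 17 lay above 0, 2 were higher over all probe sets and 11 adjusted over the list alone (camera, adjusted p = 2.25e-12). Of 15 peptidergic nociceptor markers 2 were higher over all probe sets and 6 adjusted over the list alone (adjusted p = 2.65e-05). Of 8 markers of C-fibre low-threshold mechanoreceptors 1 was higher, and 5 adjusted over the list alone (adjusted p = 2.66e-06). Of 6 thermosensory TRP channels 1 was higher, and 3 adjusted over the list alone (adjusted p = 2.40e-05). Of 13 neuropeptide genes 3 were higher, and 5 adjusted over the list alone (adjusted p = 1.13e-06). Each of these 5 lists had adjusted p = 0.199 with an estimated correlation, in a test limited to 2 degrees of freedom. The estimated correlation was 0.06 for the nonpeptidergic list. For the others, in the order given, it was -0.06, -0.11, -0.16 and -0.01, below the preset 0.01. Correlated genes therefore do not account for the higher p of these others. The lists share members, and Trpv1 and Tac1 are each counted in 2 of them. The median difference was 0.30 for the nonpeptidergic and 0.20 for the peptidergic list, against 0.13 for 18 sensory neuron transcription factors. Arrays were scaled to a common mean, so each shift is relative to the other RNA on an array. Whether the shifts are particular to these neuron classes was not tested. By each gene's brightest probe set, the 11 voltage-gated sodium channel genes had 0 past when adjusted over all probe sets, and 6 higher and 1 lower adjusted over the list alone. Their list was shifted up (adjusted p = 0.00265), with adjusted p = 0.337 with an estimated correlation and 0.0883 without sample-2 array 1. Scn2a measured 33.7 ± 7.98 and 55.4 ± 3.73 (adjusted p = 0.342). Of 5 tested probe sets each, 1 of Scn9a and, on the nonpeptidergic list, 1 of Plxnc1 were higher past the threshold. Both genes lie outside the rule for named genes. The sodium channel list shares members such as Scn11a with the nociceptor lists, and the neurotrophic list members such as Ret. Of 15 neurotrophic factor ligands and receptors Ret was higher, and 4 were higher adjusted over the list alone. That list was shifted up (adjusted p = 0.00642), with adjusted p = 0.454 with an estimated correlation and 0.317 without sample-1 array 2.

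Several of these calls were lost when certain arrays were left out. For Mrgpra3 the adjusted p with each array left out in turn ranged from 0.106 to 0.165, and for Ret from 0.0969 to 0.2498, above 0.05 each time. It ranged from 0.0450 to 0.245 for Tac1, under 0.05 only without sample-2 array 1, and from 0.0420 to 0.192 for Th, under 0.05 only without sample-1 array 2. For Chrnb4 it ranged from 0.0220 to 0.215, above 0.05 without sample-1 array 1 or sample-2 array 2.

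**Figure D3:**
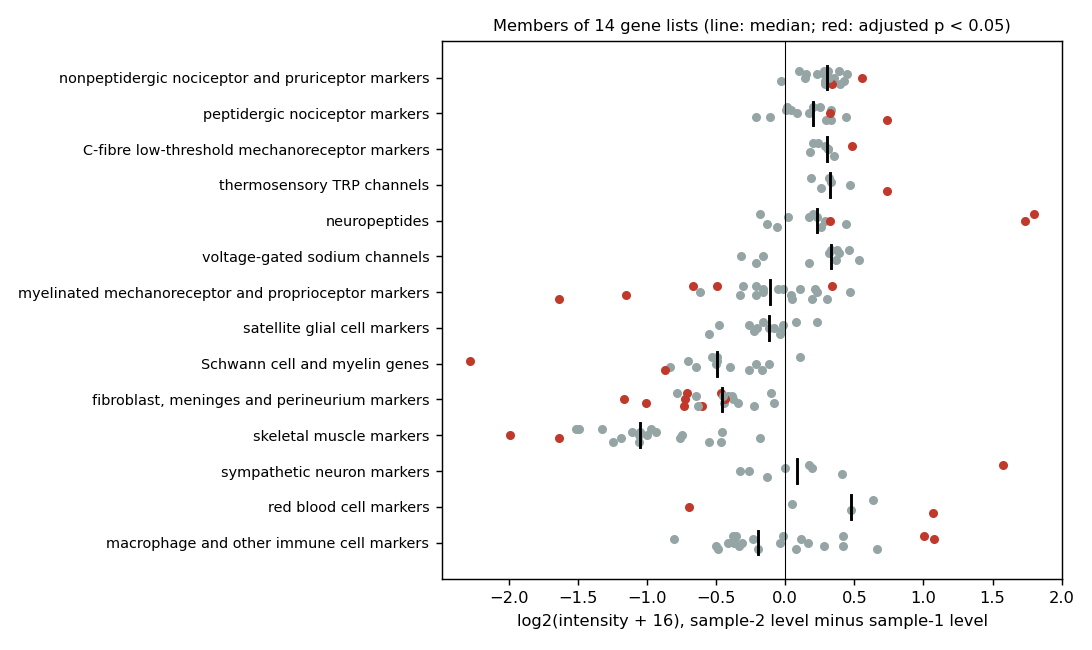
Log2(intensity + 16) at the sample-2 level minus the sample-1 level for each tested gene of 14 lists, with a black line at each list's median and genes past adjusted p 0.05 in red. The nociceptor, TRP channel and neuropeptide medians lie above 0, and the myelin, fibroblast and muscle medians below.

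Some markers of large myelinated sensory neurons fell. Pvalb fell by 1.64 ± 0.15 (adjusted p = 0.000397). Calb2, the calcium-binding protein calretinin, fell from 111 ± 24.8 to 41.0 ± 9.78 (adjusted p = 0.0256), Asic1, an acid-sensing ion channel, from 241 ± 15.4 to 146 ± 2.46 (adjusted p = 0.0355), and Cntnap2, a protein beside the nodes of myelinated axons, from 781 ± 75.7 to 547 ± 12.4 (adjusted p = 0.0474). The other tested probe sets of Cntnap2 differed by -0.20 and -0.26 and did not pass. Of the 22 tested markers of myelinated mechanoreceptors and proprioceptors 4 were lower and 1, Ret, was higher. Adjusted over the list alone, 8 were lower and 3 higher. These counts use each gene's brightest probe set. Of all tested probe sets, 3 of 4 for Ldhb and 1 each for Vsnl1 and Kcnc1 were lower past the threshold. These genes lie outside the rule for named genes. No member but Ret had a probe set higher past it. The list was shifted down (adjusted p = 0.0162), with adjusted p = 0.423 with an estimated correlation and 0.103 without Pvalb, a setting chosen after the data were seen. Shox2, a homeobox transcription factor of sensory neurons, fell from 358 ± 4.12 to 203 ± 7.51 (adjusted p = 0.0106) and was the 1 gene past over all probe sets, and adjusted over the list alone, among 18 sensory neuron transcription factors, whose list did not pass (adjusted p = 0.133). Leaving out each array in turn gave an adjusted p of 0.0722 to 0.147 for Asic1, above 0.05 each time, from 0.0453 to 0.244 for Cntnap2, under 0.05 only without sample-1 array 1, and from 0.0149 to 0.136 for Calb2, above 0.05 without sample-1 array 2 or sample-2 array 2.

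Markers on the skeletal muscle list were mostly several-fold higher on sample-1 array 2 than on the other sample-1 array, which lay near the sample-2 arrays (median difference 0.04, 10 of 19 genes above). Myh2, a fast myosin heavy chain, fell from 81.2 ± 54.3 to 6.92 ± 6.73 (adjusted p = 0.0319), below the filter level, so that its fitted difference of -1.99 ± 0.35 depends on the pseudocount. Smpx, a small protein of striated muscle, fell from 186 ± 53.1 to 53.5 ± 12.9 (adjusted p = 0.00628). It is not on that list and still passed without each array in turn, with an adjusted p from 0.000974 to 0.0269, the highest without sample-1 array 2. Acta1, skeletal actin, measured 459 on sample-1 array 1, 1714 on sample-1 array 2 and 445 and 268 on the sample-2 arrays, and Ckm, muscle creatine kinase, 193, 1012, 244 and 143. Pvalb measured 1217 and 1751 on the sample-1 arrays and 508 and 415 on the sample-2 arrays. Of 20 muscle markers Myh2 and Pvalb were lower over all probe sets, and 7 adjusted over the list alone. The list was shifted down (mean -1.04, adjusted p = 1.89e-11), with adjusted p = 0.423 with an estimated correlation and a mean of -0.17 (adjusted p = 0.317) without sample-1 array 2. With each array left out in turn the adjusted p of Myh2 ranged from 0.00167 to 0.1505, above 0.05 without sample-1 array 2 or sample-2 array 1.

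**Figure D4:**
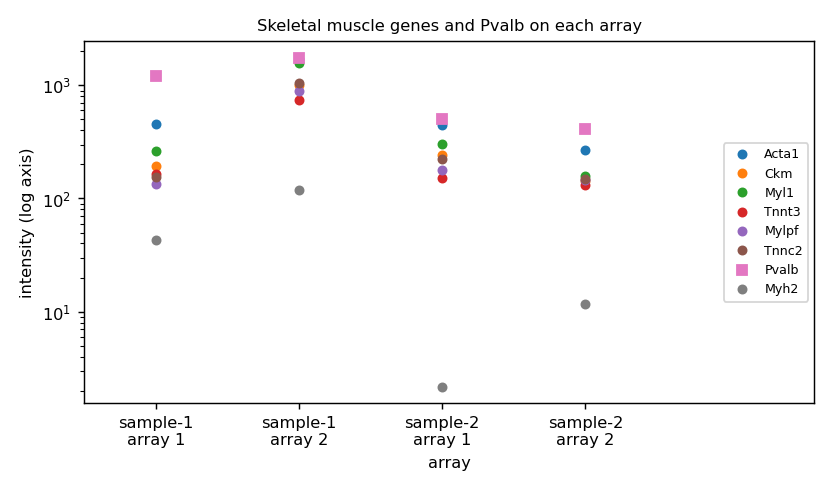
Intensity (log axis) of 7 skeletal muscle genes (circles) and Pvalb (squares) on each of the 4 arrays. Muscle genes such as Acta1 and Ckm were highest on sample-1 array 2, at 1714 and 1012, while Pvalb was high on both sample-1 arrays, at 1217 and 1751.

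Some genes of connective tissue and of Schwann cells fell, with counts given for each list. Ptgds, a prostaglandin D synthase made by the meninges, fell from 4989.7 ± 618 to 2203 ± 58.4 (-1.17 ± 0.08, adjusted p = 9.37e-05), and Mfap5, a protein of microfibrils, from 605 ± 43.2 to 295 ± 59.99 (adjusted p = 0.00628). The collagen gene Col1a2 fell from 1529 ± 192 to 919.8 ± 198 (adjusted p = 0.0313) and the proteoglycan gene Lum from 508 ± 45.7 to 301 ± 30.8 (adjusted p = 0.0172). All 20 markers of fibroblasts, meninges and perineurium lay below 0, 8 were lower over all probe sets and 15 adjusted over the list alone. The list was shifted down (adjusted p = 7.86e-20), with adjusted p = 0.199 with an estimated correlation. Pmp2 fell by 2.28 ± 0.20 (adjusted p = 0.000366), and Ugt8a, an enzyme of myelin galactolipid synthesis, from 1024 ± 239 to 554 ± 138 (adjusted p = 0.0429). These were the 2 of 15 Schwann cell and myelin genes whose brightest probe set passed over all probe sets, against 8, all lower, adjusted over the list alone. Of the 8 tested probe sets of Mbp, on this list but outside the rule for named genes, 1 was lower past the threshold. That list was shifted down (adjusted p = 3.76e-10), with adjusted p = 0.382 with an estimated correlation. Of 13 satellite glial cell markers 0 passed over all probe sets and 1 was lower adjusted over the list alone. Their list was shifted down (adjusted p = 0.0230), with adjusted p = 0.337 with an estimated correlation, 0.211 without sample-1 array 1, 0.222 without sample-2 array 2 and 0.295 with the mean of each gene's probe sets. With each array left out in turn the adjusted p ranged from 0.00198 to 0.111 for Col1a2, from 0.0129 to 0.0818 for Lum and from 0.00647 to 0.143 for Ugt8a, above 0.05 for each without sample-1 array 1 or sample-2 array 2.

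Ntn5, of the netrin family, fell from 77.4 ± 10.7 to 12.9 ± 8.68 (adjusted p = 0.0106), below the filter level, so that its fitted difference of -1.72 ± 0.24 depends on the pseudocount. Vstm2b fell from 136 ± 10.7 to 42.5 ± 7.58 (adjusted p = 0.00407) and Serpind1, a thrombin inhibitor, from 143 ± 21.7 to 47.1 ± 10.1 (adjusted p = 0.00668). Pcdh8, a protocadherin, fell from 164 ± 15.1 to 59.6 ± 3.16 (adjusted p = 0.00376) and was the 1 gene past over all probe sets of 19 protocadherins and cadherins. Col18a1, a basement membrane collagen, fell from 98.0 ± 20.9 to 32.1 ± 4.66 (-1.24 ± 0.19, adjusted p = 0.0172), while its other tested probe set differed by -0.19. Gjb6, a connexin, fell from 80.4 ± 5.77 to 26.2 ± 2.33 (adjusted p = 0.0172). Without each array in turn the adjusted p ranged from 0.00208 to 0.0505 for Ntn5, above 0.05 without sample-1 array 2, and from 0.0164 to 0.102 for Col18a1 and 0.0202 to 0.0875 for Gjb6, above 0.05 without sample-1 array 1.

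Some blood cell genes rose. S100a9 rose by 1.08 ± 0.12 (adjusted p = 0.00214) and S100a8, its binding partner, from 1348 ± 202 to 2728 ± 461 (adjusted p = 0.00365). The neutrophil genes Lcn2 and Camp rose from 169 ± 43.2 to 386 ± 27.6 (adjusted p = 0.00677) and from 203 ± 33.6 to 449.6 ± 93.6 (adjusted p = 0.00993), and Chil3, a chitinase-like protein of myeloid cells, from 102 ± 11.54 to 235 ± 21.1 (adjusted p = 0.00536). Slc4a1, the anion exchanger of red cells, rose from 101 ± 25.1 to 232 ± 70.1 (adjusted p = 0.0363), while Car2, a carbonic anhydrase that sensory neurons also express, fell from 1209.9 ± 31.6 to 742 ± 89.4 (adjusted p = 0.00869). H2-T18, a nonclassical MHC class I gene, rose from 9.73 ± 2.90 to 48.6 ± 7.19 (adjusted p = 0.0327), from below the filter level, so that its fitted difference of 1.33 ± 0.24 depends on the pseudocount. Of 23 macrophage and other immune cell markers S100a8 and S100a9 were higher, and 4 higher and 5 lower adjusted over the list alone (adjusted p = 0.524). Of 5 red blood cell markers Slc4a1 was higher and Car2 lower, and 2 higher and 1 lower adjusted over the list alone. Their list did not pass (adjusted p = 0.149), although it did without sample-2 array 1 (adjusted p = 0.004997). The adjusted p of Slc4a1 with each array left out in turn ranged from 0.00742 to 0.173, above 0.05 without sample-1 array 1 or sample-2 array 2, and that of H2-T18 from 0.0418 to 0.191, under 0.05 only without sample-1 array 2.

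Markers of the remaining tissues and states gave no list call in the fit as designed. Of 8 sympathetic neuron markers Chrna3 was higher, also adjusted over the list alone (adjusted p = 0.149), and the list passed without sample-1 array 1 (adjusted p = 0.0299), without sample-2 array 2 (adjusted p = 0.0200) or with the array number as a block (adjusted p = 0.0429). The 7 tested spinal cord markers had 0 past over all probe sets and 1 lower adjusted over the list alone (adjusted p = 0.367), with a mean of -0.11 and a median of 0.01. For 17 endothelial and mural cell markers (adjusted p = 0.277) the counts were 0 over all probe sets, and 1 higher and 1 lower adjusted over the list alone. For 9 adipose, cartilage and bone markers (adjusted p = 0.524) they were 0 and 1 lower. Among 14 nerve injury genes (adjusted p = 0.759) 0 passed over all probe sets, and 2 were higher and 3 lower adjusted over the list alone, and among 22 immediate early genes (adjusted p = 0.158) 0 passed and 1 was lower. Atf3, a marker of injured neurons, measured 105 ± 17.4 and 68.7 ± 5.16 (adjusted p = 0.241). The 7 sex-linked genes had 0 past either way (adjusted p = 0.182).

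Of the remaining lists 2 were shifted, both down. The 29 genes of mitochondrial oxidative phosphorylation had a mean difference of -0.08 with 0 past either way (adjusted p = 0.00104), with adjusted p = 0.485 with an estimated correlation and 0.127 without sample-1 array 2. The retinoic acid pathway list, with 14 tested genes, shares Aldh1a1, Aldh1a2 and Crabp2 with the fibroblast list and is not independent of it. It had 0 past over all probe sets and 2 lower adjusted over the list alone (camera, adjusted p = 0.0230). That list had adjusted p = 0.337 with an estimated correlation, 0.0517 without sample-1 array 1 and 0.0966 without sample-2 array 2. Rarg, a retinoic acid receptor, measured 271 ± 55.3 and 159.8 ± 11.1 (adjusted p = 0.0592), while its other tested probe set differed by 0.49 and did not pass either. Not past were 12 other axial patterning factors (adjusted p = 0.182, 0 past either way), 20 potassium channels (adjusted p = 0.568, 0 past, and 1 higher and 1 lower adjusted over the list alone), 19 ribosomal protein genes (adjusted p = 0.137, 0 past either way), 30 axon guidance genes (adjusted p = 0.229, 0 past, and 1 higher and 1 lower adjusted over the list alone) and the 19 protocadherins and cadherins (adjusted p = 0.182, 3 higher and 1 lower adjusted over the list alone). Kcna6, a potassium channel gene, differed by 0.63 at its brightest probe set (limma, adjusted p = 0.0808). Another of its probe sets differed by -0.84 and passed (adjusted p = 0.0327). Slit2, an axon guidance ligand, measured 189 ± 28.3 and 97.9 ± 24.7 (adjusted p = 0.0510). Plxnc1, also on the axon guidance list and outside the rule for named genes, had 1 of 5 tested probe sets higher past the threshold. In all, 16 of 32 lists passed camera with the preset correlation. With an estimated correlation 0 passed, in a test limited to 2 degrees of freedom that had little power. A directional fry test, which asks whether a list's genes move one way, called 6. Those 6 were HOX paralog groups 10 to 13, both nociceptor lists, C-fibre mechanoreceptors, TRP channels and neuropeptides. Apart from the HOX list these share members, such as Trpv1 and Tac1, and are not independent.

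Of the 40 genes past the threshold that the rule named, 21 still passed and 40 kept their sign without each array in turn. Of 52 genes past the threshold with several tested probe sets, all probe sets passed for 8, among them Ptgds, Chrna3 and Pcdh8, and a probe set had the other sign for 2.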

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

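The list test without Pvalb was chosen only after the result was seen, and the other alternatives were fixed before. Of 168 probe sets past the threshold (60 higher, 108 lower), 4 (2 and 2) passed without the filter on low signal, 1 (1 and 0) without the intensity trend, 10 (6 and 4) at a minimum of 1.5-fold and 104 (36 and 68) with arrays centred on their medians. The prior degrees of freedom were 4.69 without the filter and 3.17 without the trend, against 9.71, and the cause was not tested further. Without each array in turn, where the lone array of a level is assumed to vary like the others, 102 to 241 passed, 34 to 67 higher and 54 to 174 lower. The low totals were 102 without sample-2 array 2 and 115 without sample-1 array 2, and the high one 241 without sample-2 array 1. Counts moved by less than 1.5 times with pseudocounts of 1 (139) and 64 (180), a filter at the 60th percentile (197), quantile normalization (167) and without _x_at and _s_at probe sets (168). The labels do not say what arrays of the same number share, and their deviations from the level means correlated at 0.026. With the replicate block 793 passed (331 and 462), and the prior degrees of freedom were 25.9 against 9.71. The cause of the higher count was not tested. In every setting the probe sets among the 168 that were tested kept their direction. The filter, trend, minimum fold, suffix and block settings leave fitted differences unchanged, so they could not turn it. With an array left out, many of the 168 no longer passed, and probe sets outside the 168 did. Of the 32 lists 16 passed, against 0 with an estimated correlation, 6 with directional fry, and 13 to 20 in the other settings, with 13 reached without sample-1 array 2 and 20 with fry on mixed directions, and no list past the threshold turned its direction. The 0 with an estimated correlation says little about the lists, because that test had 2 degrees of freedom. Lists were not tested with a pseudocount of 64, a filter at the 60th percentile or centring on array medians. Nor were they tested without the trend, at a minimum of 1.5-fold or without _x_at and _s_at probe sets. The myelinated neuron list did not pass without Pvalb (camera, adjusted p = 0.103). Signal over background limits Hoxd10, Hoxd11, H2-T18, Ntn5 and Myh2, which lay below the filter level of 14.3 at one level.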

Other observations

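The tests of chance splits and of muscle genes on sample-1 array 1 were chosen only after the result was seen, and the neutrophil and marrow lists were written after the genes with the largest differences were known but before the values of the marrow genes were looked up. The requirement that an interval lie on one side of 0 for blood and for myelinated neurons, and that both sample-1 arrays carry the muscle signal, was also added after the values were seen. All intervals below resample genes, which can vary together, and leave out the spread between arrays.

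Outside the rule for named genes, and picked after their values were seen, 4 further genes with known signalling roles passed the threshold. Esr1, an estrogen receptor, rose from 131 ± 0.535 (SD, n = 2) to 278 ± 8.30, with 1 of its 3 tested probe sets past the threshold (adjusted p = 0.00376). Htr3a, a serotonin-gated ion channel, rose from 816 ± 4.96 to 1167 ± 62.7 (adjusted p = 0.0236). Esrrg, an orphan nuclear receptor, fell from 231 ± 17.7 to 118 ± 7.78 (adjusted p = 0.0121), and Shh, a secreted morphogen, from 734 ± 15.0 to 508 ± 21.9 (adjusted p = 0.0313), while its other probe set differed by -0.01. Without each array in turn the adjusted p of Esr1 stayed at or under 0.0210, and that of Esrrg reached 0.0577 without sample-1 array 2. That of Htr3a reached 0.115 and that of Shh 0.135, both under 0.05 only without sample-2 array 1. The 18S ribosomal RNA control probe set at the 5' end measured 1179 and 559 on the sample-1 arrays and 688 and 6493 on the sample-2 arrays.

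Of 14 tested neutrophil genes 7 were higher at the sample-2 level past the threshold and 13 lay above 0, with a median log2 difference of 0.83 (interval 0.64 to 1.04), although the list holds genes already seen to be higher. The bounds for blood and marrow were fixed as shares of that median, so their size rests on those genes too. One hypothesis is more blood in the sample-2 ganglia, for which 5 red blood cell genes had a median of 0.47, past the bound set in advance, but with an interval of -0.70 to 1.07 and Slc4a1 higher against Car2, which neurons also express, lower, so the test left it open. Outside that test, a probe set shared by alpha-globin genes rose from 507 ± 74.8 to 987 ± 266 (adjusted p = 0.0238), and 3 shared by immunoglobulin kappa segments rose by 1.32 to 1.54, as blood or marrow would both bring. Another is bone marrow carried over in the dissection, for which 14 marrow precursor genes had a median of 0.32 (0.01 to 0.42) with 0 past the threshold, between the 2 bounds set in advance. Blood and marrow cannot be told apart by these genes, and a difference between the levels themselves stays open and untested.

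Pvalb was lower at the sample-2 level, and the hypothesis of muscle attached to the sample-1 ganglia may account for part of it, because the 19 other muscle genes had a median of -1.05 (interval -1.19 to -0.76). That met the bound set in advance, yet the shift came from sample-1 array 2, where their median lay 2.15 (1.54 to 2.34) above the sample-2 arrays and Pvalb 1.89 above. On sample-1 array 1 the muscle median was 0.0389 (-0.25 to 0.36), with 10 of 19 genes above, while Pvalb lay 1.38 above. For the set as a whole this argues against muscle as the source of Pvalb on that array. Some muscle genes were higher there, such as Myh2 at 42.8 against 2.16 and 11.7. Smpx, outside the set, still differed by -1.25 without sample-1 array 2. A different make-up of large myelinated neurons is the other hypothesis, and the 21 other tested markers had a median of -0.0547 (-0.22 to 0.10), 3 lower and 1 higher, which met the bound set in advance, but the interval spans 0. Outside that test, a probe set shared by Etv1, on the same list, and Gm5454 fell from 648 ± 12.6 to 404 ± 9.61 (limma, adjusted p = 0.0106). Further probe sets of Ldhb, Vsnl1 and Kcnc1 were also lower past the threshold. How much muscle RNA adds to Pvalb on sample-1 array 2 and the neuron make-up stay open.

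Chrna3, Penk and Cartpt were higher at the sample-2 level, and sympathetic ganglion tissue in the dissection was weighed as a possible source. The 7 other tested sympathetic markers had a median of -0.00505 (interval -0.27 to 0.19), under the bound of 0.4 set in advance, which argues against that tissue as the source of the pattern as a whole. Dbh, the noradrenaline-making enzyme, measured 22.0 ± 14.5 and 25.8 ± 1.71, and Npy 46.3 ± 3.63 and 42.8 ± 21.2, both at low intensity. Th (702 ± 65.6 to 987 ± 47.3) and Chrnb4 (36.8 ± 12.4 to 95.2 ± 18.6), which sympathetic neurons also express, rose past the threshold, and a sympathetic share in these 2 genes stays open. A difference between sensory neurons of the levels stays a hypothesis that was not tested.

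The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The levels gave 168 probe sets and the other splits at most 0 with limma, where an unadjusted p under 0.05 was found for 2933 probe sets between the levels and for 817 and 639 in the other splits. As many as 168 were found in 1 of the 3 splits, that of the levels. In the other splits any difference between levels falls within the pairs and widens their spread. Fewer calls there therefore do not measure chance.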
